A study of Homo sapiens with 6 samples.

How the data were processed

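The series holds 6 RNA-seq libraries of the human glioblastoma cell line U251, 3 untreated and 3 given taurochenodeoxycholic acid (TCDCA). The labels write "Tau" for the treated libraries and the design text names the acid. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build GRCh38, without saying which step each served. The strand setting of the counting, whether poly(A) RNA was selected, whether a vehicle was given to the controls and any filter on reads are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

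The authors deposited a table of raw counts per gene, 1 column per library, and a table of FPKM. The counts as deposited are whole numbers that sum to 14580261 to 17004337 per library. The deposited FPKM equalled the counts divided by the gene length in the table and by 1 library size per sample, so both tables hold the same measurement. The number of columns of per-sample values not used was 0. Coordinates are those of the deposited table, and 58735 of 58735 genes had the same start, end and strand in GENCODE release 29. For 27 genes the deposited symbol had been turned into a date, and the symbol was restored from the gene identifier.

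Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, after filterByExpr and TMM normalisation, with the group as the only term and Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. CPM are TMM-normalised. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 3 members were tested, adjusted over the lists, with an estimated correlation and fry beside it. The 32 lists, of which 30 could be tested, cover pathways and markers of other cell types. They were fixed before the data were examined, as were the tests and the rule for naming genes. For 3 listed symbols no gene was found.

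The rule named the 12 largest rises and 12 largest falls among protein-coding genes past the threshold with non-overlapping groups, a symbol and a mean of at least 5 CPM. It also named the 5 smallest p under the same limits of CPM and symbol, up to 4 members with the smallest p of each list that was called or had at least 2 members past the threshold, and 13 single genes whatever their result.

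The alternatives were other scalings (RLE, upper quartile, library size only), no filter on low counts, a filter of 1 CPM in 3 libraries, protein-coding genes only, DESeq2 1.42.0, limma-voom, edgeR with robust dispersion, the replicate number as a block, each library left out in turn, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM over 0.5 in 3 libraries or no filter. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. A correction of each library's trend with GC content and transcript length was added after seeing the data. For DESeq2 and for that correction, lists were tested on signed z values of the genes.

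The test was checked on simulated data for this comparison, with 200 of 15970 genes changed in each of 5 runs. It recovered 35.2% of genes changed by 0.5 (log2), 77.6% of those changed by 1 and 94.2% of those changed by 2, with 0 of the wrong sign, and 6.89% of calls were false. In the simulation genes varied independently and no control stood apart as control 1 did, so these rates may differ in the real data. A list changed by 0.5 was called in 5 of 5 runs and 0 of 145 unchanged lists were called, in data simulated without correlation between genes. Intervals and floors for low counts cover counting error only. The results of 2 genes that the naming rule selected were left out and are not reported here.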

Results

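RNA was sequenced from 6 libraries of U251, an established human glioblastoma cell line. Per the labels, 3 libraries came from cells without special treatment (control) and 3 from cells given 200 µM "Tau" for 24 h, read here from the series text as taurochenodeoxycholic acid (TCDCA). TCDCA is the taurine conjugate of chenodeoxycholic acid, a bile acid. The series title asks by which mechanism this acid acts in U251 cells, and the design implies 1 comparison, treated against untreated. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total counts were 16941023, 16990197 and 16479929 in controls 1, 2 and 3 and 17004337, 15553943 and 14580261 in TCDCA 1, 2 and 3. Mitochondrially encoded genes took 3.02% to 3.8% of the counts, and the 10 most abundant genes 5.05% to 5.8%.

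Control 1 stood apart from controls 2 and 3. The chi-square of the counts over genes, per degree of freedom, was 31.4 between controls 1 and 2 and 31.0 between controls 1 and 3, against 2.68 between controls 2 and 3 and 2.36 to 4.72 between treated libraries. No pair of libraries agreed within sampling noise, so none was merged with another, which does not show that they came from separate cultures. The first principal component, with 40.9% of the variance, placed control 1 at -45.5, controls 2 and 3 at -3.08 and -4.36 and the treated libraries at positive values of up to 19.8. On the second, with 24.9%, control 1 lay at 16.6, on the side of the treated libraries (10.2, 10 and 12.5). Controls 2 and 3 lay at -24 and -25.3. For this reason the deviation of control 1 is given beside each gene list below, as the median log2 difference from the mean of controls 2 and 3.

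**Figure D1:**
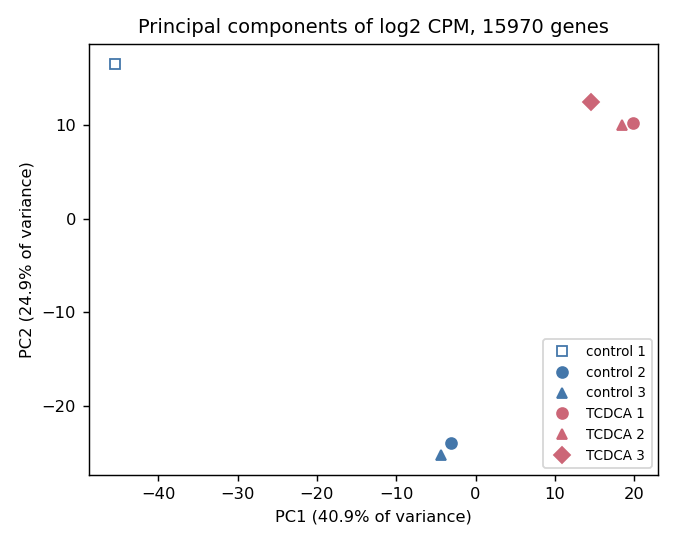
Principal components of log2 CPM over the 15970 tested genes, PC1 (40.9% of variance) on the x axis and PC2 (24.9%) on the y axis, 1 point per library. Control 1 (open square) lies at -45.5 on PC1, while controls 2 and 3 lie close together and the 3 treated libraries form a cluster of their own.

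After TCDCA, genes of the integrated stress response and genes of sterol and fatty acid synthesis rose, and collagen and heat shock genes were among those that fell. The largest rise among the changed genes was that of CHAC1, a glutathione-degrading enzyme induced by ATF4 and CHOP, from 19.4 ± 11.2 to 203.3 ± 15.7 CPM (mean ± SD, n = 3 per group), or 10.5-fold. HMGCS1, which makes the HMG-CoA used for sterols, rose 3.05-fold from 103.3 ± 11.5 to 315.0 ± 15.9 CPM. HSPA8, the constitutive HSC70 chaperone, fell from 958.9 ± 84.3 to 481.9 ± 35.2 CPM, and COL1A1, a chain of type I collagen, fell from 12.4 ± 4.41 to 4.01 ± 0.627 CPM. By edgeR's quasi-likelihood test, 703 of 15970 tested genes changed at a Benjamini-Hochberg adjusted p under 0.05, 407 higher and 296 lower with TCDCA, and 114 of them by at least 2-fold, 78 higher and 36 lower. The median size of the 703 changes was 0.565 (log2), and 370 were under 1.5-fold.

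The count depended on each library. Without control 1 it was 2782 genes, 1355 higher and 1427 lower, 231 of them by at least 2-fold, and all 703 genes were among them. Without control 2 it was 397 and without control 3 it was 250, and without TCDCA 1, 2 or 3 it was 88, 92 or 119. Of the 81 genes that the naming rule selected and that passed, 28 passed in all 6 of these fits and 53 lost the call in at least 1. On the deposited FPKM with a pseudocount of 1, 285 genes changed, 57 when no filter was set on low values, and 30 and 63 of the 81 genes lost the call (limma). The 63 included 12 of the 28, though 0 of the 28 were among the 30. The 12 were CHAC1, ATF3, MTHFD2, CEBPG, PPP1R15A, FASN and SCD, with adjusted p of 0.0784, 0.084, 0.0946, 0.0507, 0.0507, 0.0513 and 0.36, and ACSS2, PLK3, LIF, SPRY2 and PDGFRA, with 0.0749, 0.0501, 0.0598, 0.0588 and 0.0514, the largest values over all alternatives for these genes. The genes given with full statistics below are among the 28 unless a left-out library is named, and adjusted p "up to" a value are the largest over the 6 fits that each left out 1 library. Control 1 was the library seen to stand apart, and controls 2 and 3 lay close together. Leaving it out narrows the spread between controls, so p-values and counts without control 1, here and below, are likely too favourable and are no independent support.

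Among protein-coding genes of at least 5 CPM, the largest falls after SCUBE3 were those of COL1A1, TUBA4A, LFNG and OLFML2A. SCUBE3, a secreted glycoprotein, fell 3.43-fold from 85.0 ± 56.2 to 24.8 ± 0.886 CPM (log2 -1.78, adjusted p 0.0331, edgeR), TUBA4A, an alpha-tubulin that overlaps STK16, fell 2.59-fold and LFNG, a glycosyltransferase that modifies Notch receptors, fell 2.15-fold. Control 1 had 149.8 CPM of SCUBE3 against 50.2 and 55.0 CPM in controls 2 and 3, and without control 1 the log2 change was -1.08. HMCN1 and MEGF6, which encode extracellular proteins, fell 2.06-fold and 2-fold and moved to a log2 change of -0.63 each without control 1. SCUBE3, TUBA4A, HMCN1 and MEGF6 lost the call without TCDCA 1, 2 or 3, with adjusted p up to 0.168, 0.131, 0.186 and 0.19, and TUBA4A also without control 2 and HMCN1 without control 3. LFNG lost it without TCDCA 1 or 2, with an adjusted p up to 0.0826. RGPD5 rose 3.19-fold (adjusted p 0.0266, edgeR; up to 0.15, without control 3 or any treated library), but it shares nearly all of its sequence with other RGPD genes, so its value is uncertain.

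**Figure D2:**
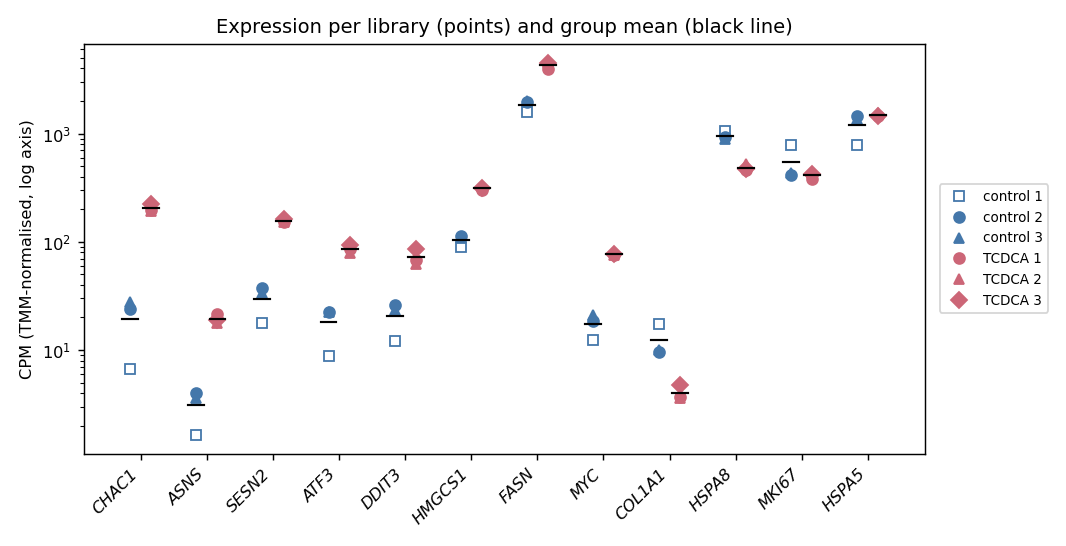
CPM (TMM-normalised, log axis) of 12 genes in each of the 6 libraries (points) with the group means (black lines). CHAC1 had a mean of 19.4 CPM in the controls and 203.3 CPM in the treated libraries, with control 1 (open squares) lowest, while MKI67 and HSPA5, which did not pass the test, had control 1 apart from all other libraries.

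Of the 35 tested genes of the integrated stress response, the program that ATF4 drives when translation initiation is restrained, 28 rose, 0 fell and 7 did not pass. Adjusted over the list alone, 33 rose. ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542 in GRCh38), rose 6.25-fold from 3.10 ± 1.28 to 19.4 ± 1.74 CPM (log2 2.64, SE 0.251, adjusted p 0.00132, edgeR). SESN2, a stress-induced inhibitor of mTORC1 (chromosome 1, 28259527 to 28282491), rose 5.24-fold (log2 2.39, SE 0.217, adjusted p 0.00121, edgeR), and CHAC1 (chromosome 15, 40952962 to 40956519) rose with a log2 change of 3.39 (SE 0.381, adjusted p 0.00299, edgeR). ATF3, a stress-induced transcription factor, rose 4.75-fold and MTHFD2, a mitochondrial folate enzyme, 3.09-fold. DDIT3, which encodes CHOP, rose 3.51-fold (adjusted p 0.00581, edgeR), and it lost the call without TCDCA 3 (adjusted p 0.0531; 2.08e-60 to 0.103 over all alternatives). Reads of DDIT3 and of ASNS could be shared with overlapping genes, MARS and MBD6 for DDIT3 and AC079781.5 and AC005326.1 for ASNS. The list median was 1.15 (log2; camera adjusted p 5.33e-61, limma), with adjusted p = 0.107 with an estimated correlation. Control 1 had a median of -0.82 against controls 2 and 3 over this list. Without control 1, 34 of 35 rose, the median was 0.85 and the list was then called with an estimated correlation too (adjusted p = 0.0307 with an estimated correlation).

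The list of endoplasmic reticulum chaperones, which also holds genes of the unfolded protein response, of degradation and of transport, was not called (median 0.03, camera adjusted p 0.207, limma). Of its 26 tested members 2 rose, 0 fell and 24 did not pass, with 2 that rose when adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, rose 2.17-fold (adjusted p 0.00642, edgeR), and it lost the call without TCDCA 1 or TCDCA 3, with an adjusted p up to 0.0554. HERPUD1, a component of endoplasmic reticulum degradation, rose 1.90-fold (adjusted p 0.0233, edgeR), and it lost the call without control 3 or any treated library, with an adjusted p up to 0.127. HSPA5, which encodes the chaperone BiP, was at 1196 ± 365 CPM in controls and 1484 ± 65.6 CPM with TCDCA (adjusted p 0.4, edgeR; 0.00906 with no filter on low counts). In control 1 the median was -0.23 against controls 2 and 3. The list was called higher without control 2 (median 0.09, camera adjusted p 0.0178) and with DESeq2 (adjusted p 0.0487). Without control 1 its median was -0.00625 (camera adjusted p 0.467), with 4 of 26 that rose and 4 that fell. In that fit XBP1, HERPUD1, ERN1 and DNAJB9 rose, by log2 0.245 to 0.939. The chaperones and folding enzymes HSP90B1, PDIA3, PDIA4 and CALR fell, by log2 -0.163 to -0.185.

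Cholesterol synthesis genes, which SREBF2 controls, rose as a list. Of 24 tested members 16 rose, 0 fell and 8 did not pass, and 21 rose when adjusted over the list alone. HMGCS1 (chromosome 5, 43289395 to 43313512) rose with a log2 change of 1.61 (SE 0.0952, adjusted p 0.000418, edgeR), the smallest p of all tested genes. MVD, mevalonate diphosphate decarboxylase (chromosome 16, 88651935 to 88663161), rose 2.35-fold from 25.5 ± 1.14 to 60.0 ± 5.69 CPM (log2 1.23, SE 0.0921, adjusted p 0.000583, edgeR). The list median was 0.76 (log2; camera adjusted p 3.77e-61, limma), and the call held with an estimated correlation (adjusted p = 0.0193 with an estimated correlation). Control 1 lay close to controls 2 and 3, with a median of 0.05 against them. Without control 1, 23 of 24 rose and the median was 0.74 (adjusted p = 0.0327 with an estimated correlation).

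Fatty acid synthesis genes rose with them. Of 13 tested members 7 rose, 0 fell and 6 did not pass, and 7 rose when adjusted over the list alone. FASN, fatty acid synthase, rose 2.34-fold from 1848 ± 229 to 4332 ± 314 CPM, and SCD, the stearoyl-CoA desaturase, rose 2.02-fold from 6163 ± 986 to 12460 ± 288 CPM. FADS1, a fatty acid desaturase that overlaps FADS2, rose 1.97-fold and ACSS2, which makes acetyl-CoA from acetate and overlaps GGT7, 2.04-fold. The list median was 0.51 (camera adjusted p 2.67e-16, limma), and the call held with an estimated correlation (adjusted p = 0.0337 with an estimated correlation). Control 1 had a median of -0.32 against controls 2 and 3. Without control 1, 10 of 14 rose, 1 fell and the median was 0.57, and the call was then lost with an estimated correlation (adjusted p = 0.0617 with an estimated correlation).

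Of 30 tested immediate early genes, the first genes induced by growth factor signalling, 15 rose, 0 fell and 15 did not pass, and 20 rose when adjusted over the list alone. MYC, a transcription factor of growth, rose 4.41-fold from 17.3 ± 4.52 to 76.5 ± 0.927 CPM (log2 2.14, SE 0.16, adjusted p 0.000583, edgeR). KLF6, a zinc finger factor, rose 1.72-fold, and SPRY2 and SPRY4, feedback inhibitors of receptor tyrosine kinase signalling, rose 1.82-fold and 1.63-fold. The list median was 0.57 (camera adjusted p 1.08e-29, limma), with adjusted p = 0.107 with an estimated correlation. Control 1 had a median of -0.42 against controls 2 and 3 over these genes. Without control 1, 19 of 30 rose and the median was 0.47. TSC22D3, a leucine zipper protein also known as a glucocorticoid-induced gene and in none of these lists, rose 4.55-fold from 24.8 ± 6.36 to 112.9 ± 2.19 CPM.

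Genes of NF-kB signalling and cytokines were called higher as a list, with 4 of 31 tested members that rose, 0 that fell and 27 that did not pass, and 7 that rose when adjusted over the list alone. LIF, a cytokine of the interleukin 6 family, rose 2.97-fold from 31.4 ± 8.09 to 93.4 ± 4.82 CPM. IL6, interleukin 6, rose 2.08-fold (adjusted p 0.0187, edgeR), and it lost the call without TCDCA 1, 2 or 3, with an adjusted p up to 0.106. Across the list the median was 0.45 (camera adjusted p 1.22e-06, limma), with adjusted p = 0.563 with an estimated correlation and 0.265 by fry. Against controls 2 and 3, control 1 had a median of -1.02. Without control 1, 11 of 31 rose, 4 fell and the median was 0.20.

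The list of cAMP and CREB targets was called higher, with 3 of 17 tested members that rose, 0 that fell and 14 that did not pass, and 5 that rose when adjusted over the list alone. PDE4D, a cAMP phosphodiesterase, rose 1.67-fold and PPARGC1A, a transcriptional coactivator, 1.52-fold, and both lost the call without TCDCA 1, 2 or 3, with adjusted p up to 0.123 and 0.102. The median was 0.20 (camera adjusted p 0.000556, limma), with adjusted p = 0.245 with an estimated correlation, and in control 1 it was -0.15 against controls 2 and 3. Without control 1, 5 of 17 rose and the median was 0.18.

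The list of p53 targets was called higher, with 6 of 27 tested members that rose, 1 that fell and 20 that did not pass, and 9 that rose and 2 that fell when adjusted over the list alone. GADD45A, a stress-induced growth arrest gene, rose 2.99-fold from 46.7 ± 9.0 to 139.6 ± 9.96 CPM, PLK3, a stress-responsive kinase, 1.97-fold and CDKN1A, which encodes the cell cycle inhibitor p21, 1.49-fold. GADD45A is also known to be induced by stress without p53. The median was 0.10 (camera adjusted p 0.00107, limma), with adjusted p = 0.107 with an estimated correlation, and in control 1 it was 0.07 against controls 2 and 3. Without control 1, 10 of 27 rose, 2 fell and the median was 0.11, and without control 2 the median was 0.175. The call was lost on the deposited FPKM (adjusted p 0.0739 with a pseudocount of 1 and 0.107 with 0.1) and after a correction for GC content and length (adjusted p 0.0523), with a range of 1.65e-06 to 0.107 over all alternatives.

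Of 12 tested histone genes 3 rose, 0 fell and 9 did not pass, and 3 rose when adjusted over the list alone. HIST1H2AC rose 2.26-fold from 21.1 ± 3.24 to 47.7 ± 4.54 CPM. HIST1H2BD rose 1.87-fold and HIST2H2BE 1.93-fold, and both lost the call without any 1 of the libraries other than control 1, with adjusted p up to 0.176 and 0.199. The genes that rose are known to make polyadenylated transcripts too, outside S phase. Across the list the median was 0.56 (camera adjusted p 3.9e-06, limma), with adjusted p = 0.135 with an estimated correlation. Against controls 2 and 3, control 1 had a median of 0.31, and without control 1 the list median was 0.75, with 6 of 13 that rose.

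Among the lists called lower, that of extracellular matrix and invasion had 8 of 39 tested members that fell, 0 that rose and 31 that did not pass, and 20 that fell when adjusted over the list alone. COL1A1 (chromosome 17, 50183289 to 50201632) fell 3.09-fold (log2 -1.63, SE 0.254, adjusted p 0.0113, edgeR), and COL1A2, the other chain of type I collagen, fell 1.5-fold from 3056 ± 376 to 2039 ± 56.2 CPM. THBS1, thrombospondin 1, fell 1.73-fold. COL1A1, COL1A2 and THBS1 lost the call without TCDCA 1, 2 or 3, with adjusted p up to 0.0906, 0.12 and 0.0871, and COL1A1 also on the deposited FPKM (adjusted p 0.0866 with a pseudocount of 1). Across the list the median was -0.28 (camera adjusted p 3.22e-10, limma), with adjusted p = 0.107 with an estimated correlation. Against controls 2 and 3, control 1 had a median of 0.14. Without control 1, 25 of 39 fell, 3 rose and the median was -0.225.

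Of 22 tested heat shock genes 5 fell, 0 rose and 17 did not pass, and 7 fell and 1 rose when adjusted over the list alone. HSPA8 (chromosome 11, 123057489 to 123063230) fell 1.99-fold (log2 -0.99, SE 0.0925, adjusted p 0.00125, edgeR), and HSPA1B, an inducible HSP70, fell 1.74-fold from 80.7 ± 3.92 to 46.3 ± 1.65 CPM. HSPA1B shares nearly its whole sequence with HSPA1A, so the split of reads between them is uncertain. Across the list the median was -0.21 (camera adjusted p 1.25e-06, limma), with adjusted p = 0.243 with an estimated correlation. Control 1 differed from controls 2 and 3 by a median of 0.14. Without control 1, 7 of 22 fell, 1 rose and the median was -0.12.

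Of 41 tested interferon response genes 5 fell, 0 rose and 36 did not pass, and 7 fell when adjusted over the list alone. IFIT1, an antiviral RNA-binding protein that overlaps LIPA, fell 1.39-fold from 1365 ± 104 to 979.6 ± 12.5 CPM, and OASL, an oligoadenylate synthetase-like protein, fell 1.52-fold, and the calls ended without control 3 or any treated library, with adjusted p up to 0.116 and 0.111, and for IFIT1 also without control 2. Across the list the median was -0.17 (camera adjusted p 1.23e-05, limma), with adjusted p = 0.669 with an estimated correlation and 0.322 by fry. Control 1 differed from controls 2 and 3 by a median of -0.36. Without control 1, 33 of 41 fell, 0 rose and the median was -0.32 (adjusted p = 0.0307 with an estimated correlation), and leaving out control 2 or 3 moved the median to as little as -0.11. The list mean, in log2 CPM relative to the controls' mean, was -0.31 in control 1 and -0.176, -0.216 and -0.169 in TCDCA 1, 2 and 3. The untreated control 1 thus lay below every treated library.

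Of 36 tested DNA replication genes 2 fell, 0 rose and 34 did not pass, and 9 fell when adjusted over the list alone. PCNA, the sliding clamp of DNA polymerase, fell 1.34-fold and MCM5, a subunit of the replicative helicase, 1.56-fold, and both lost the call without TCDCA 1, 2 or 3, with adjusted p up to 0.106 and 0.201, and MCM5 also without control 3. The median was -0.25 (camera adjusted p 2.1e-06, limma), with adjusted p = 0.463 with an estimated correlation and 0.139 by fry. Control 1 had a median of 0.28 against controls 2 and 3, and without control 1 its median was -0.14, with 9 of 36 that fell. The lists of mitosis genes and of nuclear-encoded respiratory chain genes were called lower although edgeR passed 0 of 35 and 0 of 76 members, also when adjusted over the list alone. At an unadjusted p under 0.05 there were 8 and 11, DESeq2 passed 2 in each list and voom 0. Their medians were -0.35 and -0.145 (camera adjusted p 7.24e-05 and 8.9e-05, limma), each with adjusted p = 0.669 with an estimated correlation, and 0.459 and 0.384 by fry. MKI67, a proliferation marker, was at 542.9 ± 210 CPM in controls and 409.7 ± 24.2 CPM with TCDCA (adjusted p 0.319, edgeR; 0.000472 with no filter on low counts). Against controls 2 and 3, control 1 had medians of 0.76 and 0.305 over these lists. Without control 1 the medians were 0.00233 and -0.0359 and the calls were lost (adjusted p 0.723 and 0.325), and for mitosis the test then pointed down with a median above 0. In that fit 4 of 35 mitosis genes fell, ASPM, ANLN, KIF20A and BUB1B (log2 -0.304, -0.242, -0.258 and -0.233), and 2 rose, TPX2 and CENPA, and of 76 respiratory chain genes 4 fell, SDHA, UQCRC1, NDUFB4 and COX6B1, and 0 rose.

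**Figure D3:**
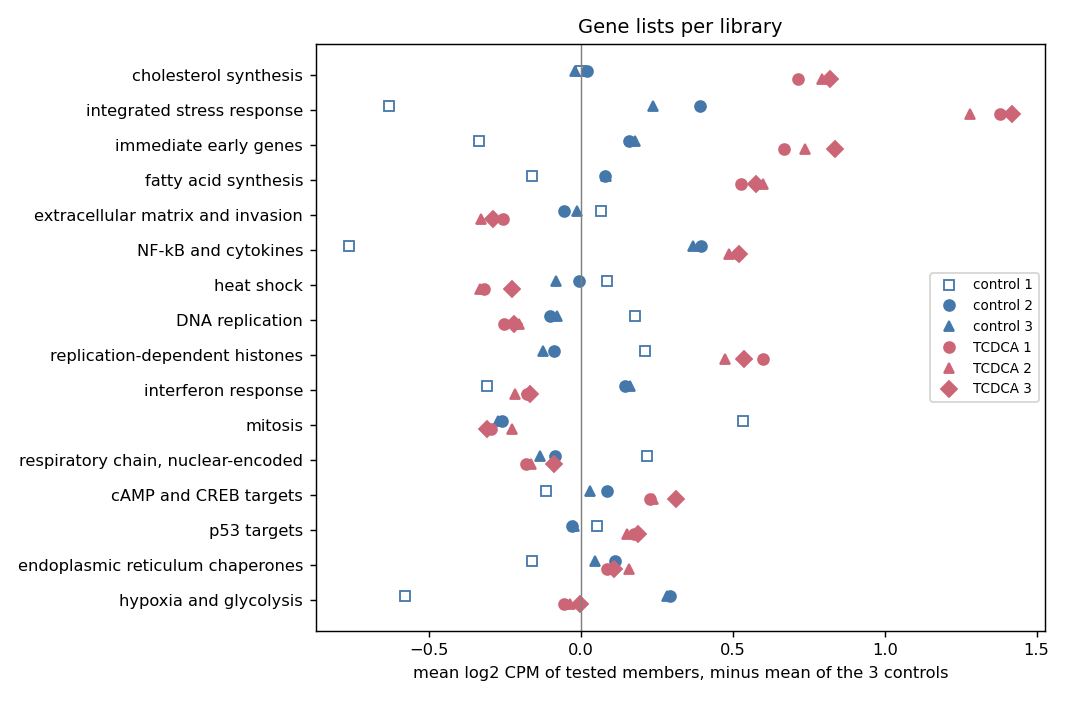
Mean log2 CPM of the tested members of 16 gene lists in each library, minus the mean of the 3 controls (x axis), with 1 row per list. The 3 treated libraries lie to the right of all controls for cholesterol synthesis, while for mitosis they lie beside controls 2 and 3 and control 1 (open square) alone stands apart.

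The receptors through which bile acids are known to signal had few counts or did not pass the test. NR1H4, the nuclear bile acid receptor FXR, had 0 to 6 counts per library, GPBAR1, the membrane receptor TGR5, 3 to 8 counts, and FGF19, a textbook FXR target, 0 to 3 counts, so none of them was tested. NR0B2 had 0 counts in all 6 libraries, which allows up to 3 counts or 0.176 to 0.206 CPM per library, and SLC51B had 1 count in TCDCA 1 and 0 in the others. VDR was at 5.41 ± 0.239 and 6.02 ± 0.425 CPM (adjusted p 0.607, edgeR), and S1PR2, which overlaps DNMT1, was at 11.4 ± 1.60 and 8.88 ± 1.43 CPM (adjusted p 0.249, edgeR). Of the 15 tested members of the list of bile acid receptors and transporters, 2 fell, 0 rose and 13 did not pass, and 2 fell when adjusted over the list alone (median -0.15, camera adjusted p 0.141, limma), and control 1 had a median of -0.0771 against controls 2 and 3. Those were the transporters ABCB4 and ABCC3, with adjusted p 0.0271 and 0.0329, and both lost the call without any 1 of the libraries other than control 1, with adjusted p up to 0.155 and 0.185.

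Camera (limma) did not call the other tested lists. Of 33 tested apoptosis genes 2 rose, 1 fell and 30 did not pass (adjusted p 0.925), and 2 rose and 2 fell when adjusted over the list alone, with a median of 0.0093, a mean of -0.0265 and a test that pointed up. PMAIP1 and BBC3, which encode the death-promoting proteins NOXA and PUMA, rose 1.45-fold and 1.81-fold, and BMF, another BH3-only gene, fell 3.5-fold from 5.22 ± 1.33 to 1.499 ± 0.45 CPM. They lost the call without TCDCA 1, and also PMAIP1 without TCDCA 2 or 3, BBC3 without TCDCA 3 and BMF without TCDCA 2, with adjusted p up to 0.0909, 0.0728 and 0.0826. Of 25 tested NRF2 and oxidative stress genes 2 rose, 2 fell and 21 did not pass (adjusted p 0.479), and 3 rose and 4 fell when adjusted over the list alone. The cystine transporter SLC7A11 rose 1.62-fold and AKR1C3, an aldo-keto reductase, fell 1.65-fold, and both lost the call without TCDCA 1, 2 or 3, with adjusted p up to 0.165 and 0.077, SLC7A11 also without control 3. Control 1 had medians of 0.019 and -0.211 against controls 2 and 3 over the apoptosis and NRF2 lists.

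Of 29 tested TGF-beta and YAP targets 2 rose, 3 fell and 24 did not pass (adjusted p 0.302), and 5 rose and 5 fell when adjusted over the list alone. AXL, a receptor tyrosine kinase, fell 1.42-fold and lost the call without TCDCA 1 or 2, with an adjusted p up to 0.0697. Of 38 tested autophagy and lysosome genes 2 rose, 1 fell and 35 did not pass (adjusted p 0.479), and 5 rose and 2 fell when adjusted over the list alone, with a test that pointed up and a median of -0.0151. WIPI1, an early autophagy protein, rose 1.49-fold and lost the call without TCDCA 2 or 3, with an adjusted p up to 0.078. Of 22 tested glial and glioma markers 1 rose, 1 fell and 20 did not pass (adjusted p 0.209), and 2 rose and 5 fell when adjusted over the list alone. PDGFRA, a growth factor receptor of glioma cells, fell 1.69-fold from 192.9 ± 20 to 114.2 ± 4.19 CPM. Control 1 had medians of 0.151, -0.0119 and 0.241 against controls 2 and 3 over these 3 lists.

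Hypoxia and glycolysis genes had 0 of 37 tested members past the test by edgeR (camera adjusted p 0.2), 9 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom, with 1 that rose and 3 that fell when adjusted over the list alone. On DESeq2 statistics the list was called lower (camera adjusted p 0.00939). Control 1 had a median of -0.84 against controls 2 and 3, and without control 1, 29 of 37 fell, 3 rose and the median was -0.32 (camera adjusted p 7.58e-24, with adjusted p = 0.0617 with an estimated correlation), while without controls 2 or 3 the test pointed up (adjusted p 0.813 and 0.856). In control 1 the list mean relative to the controls' mean was -0.578 (log2 CPM), below all treated libraries (-0.0546, -0.0353 and -0.00226). Epithelial markers, with 0 of 5 past the test by edgeR, DESeq2 and voom, 1 at an unadjusted p under 0.05 and a median of -0.74 in control 1, were called lower without control 1 (adjusted p 0.384 with it and 0.00413 without it, 4 of 5 fell, with adjusted p = 0.174 with an estimated correlation). For these markers too the list mean of control 1 lay below every treated library, at -0.47 against -0.237, -0.22 and -0.147. Of mitochondrially encoded genes 0 of 13 and of cytosolic ribosomal protein genes 0 of 77 passed by edgeR (adjusted p 0.0987 each), 3 and 2 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 0 by voom, and control 1 had medians of 0.333 and 0.305 against controls 2 and 3. Both lists were called lower with DESeq2 (adjusted p 0.00428 and 0.00745), with no filter on low counts (adjusted p 0.0269 and 0.0459), on the deposited FPKM with a pseudocount of 1 and no filter (adjusted p 0.0337 and 0.0394), without control 2 (adjusted p 0.0368 and 0.0342) and without control 3 (adjusted p 0.00324 and 0.000134), the mitochondrial list also after the GC and length correction (adjusted p 0.0385) and the ribosomal list also without TCDCA 3 (adjusted p 0.0223). Neither was called in the full comparison with an estimated correlation (adjusted p = 0.697 and 0.786 with an estimated correlation), and without control 1 the ribosomal list pointed up (median 0.0456, adjusted p 0.183).

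For the remaining lists the adjusted p was 0.141 for metallothioneins (1 of 5 rose), 0.2 for fatty acid oxidation (0 of 18), 0.77 for sterol efflux (0 of 5), 0.479 for neuron markers (1 of 9 fell) and 0.479 for endothelial markers (0 of 4). Of the lists with 0 members past edgeR's test, fatty acid oxidation, sterol efflux and endothelial markers had 4, 2 and 1 at an unadjusted p under 0.05, and DESeq2 passed 0, 1 and 0 and voom 0. Metallothioneins were called higher with DESeq2 (adjusted p 0.0311), by fry (adjusted p 0.035) and with no filter on low counts (adjusted p 0.0499). Adjusted over the list alone, 2 metallothionein list members rose and 1 fell, 0 fatty acid oxidation genes changed, 1 sterol efflux gene rose and 1 fell, and 1 neuron and 1 endothelial marker fell. The metallothionein list member that rose was SLC30A1, a zinc exporter, and the neuron marker that fell was NEFL, a neurofilament chain, both named after their values were seen. Over the 5 lists control 1 had medians of -0.165, 0.144, -0.202, 0.243 and -0.189 against controls 2 and 3. Only 2 immune and 2 oligodendrocyte markers had enough counts to be tested, so those lists were not. In all, camera called 14 of 30 tested lists, 8 higher and 6 lower, and 14 without control 1, and 2 of the 14, cholesterol and fatty acid synthesis, with an estimated correlation. Fry called 10 lists, since 5 of camera's 14 were lost and metallothioneins were added. Other splits of the same 6 libraries into groups of 3 gave 10 to 14 called lists with the preset correlation, but 0 changed genes by edgeR, with 171 to 797 genes at an unadjusted p under 0.05 against 3276 for the real groups. Those splits mix treated and control libraries in both groups, which widens the spread within groups, so their 0 says little about chance.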

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

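The correction for GC content and length was chosen after the data were seen, and all other alternatives before. With no filter on low counts, the genes changed were 1672 in place of 703, the genes higher with TCDCA 789, the genes lower with TCDCA 883 and the genes changed at least 2-fold 222. The 703 became 119 at an adjusted p under 0.01, 285 with log2(FPKM + 1) (181 higher, 104 lower, 39 by at least 2-fold), 279 with log2(FPKM + 0.1) (177, 102 and 57) and 57 with log2(FPKM + 1) and no filter (42, 15 and 15). DESeq2 called 994 genes, 467 of them lower. Leaving out 1 library gave 88 to 2782 changed genes, 76 to 1355 higher, 11 to 1427 lower and 40 to 231 by at least 2-fold. Camera called 2 lists with an estimated correlation, against 14. None of the 703 genes with a value turned its direction in any of these fits. All 703 had non-overlapping groups, so leaving out 1 library could hardly have turned them. With the scalings RLE, upper quartile and library size only, with voom and with robust dispersion, 664 to 743 genes changed. The balance of 407 higher and 296 lower depended on the scaling, with 351 and 348 by upper quartile and 445 and 240 by library size only. Apart from a fit with fewer libraries, the cause was not tested.

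With the replicate number as a block, 275 genes changed, 190 higher and 85 lower, and 14 lists were called. The labels do not say whether the numbers pair the libraries. Same-numbered libraries had correlations of deviations of -0.059, 0.015 and -0.082, the others -0.04 to 0.088, and not every library correlated best with its own number. With 3 libraries per group and control 1 far from controls 2 and 3, these values show no pairing but cannot exclude it.

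No named gene reversed. Some lists that were not called changed direction, none past the threshold where it changed. Apoptosis did so with adjusted p 0.699 with log2(FPKM + 1), 0.627 with log2(FPKM + 0.1), 0.927 with log2(FPKM + 1) and no filter, 0.93 with the GC and length correction and 1 without control 2. Neuron markers did so at 0.934 and 0.905 with log2(FPKM + 1) and log2(FPKM + 0.1), cytosolic ribosomal proteins at 0.183 without control 1, NRF2 and oxidative stress at 0.856 without control 2, and hypoxia and glycolysis at 0.813 without control 2 and 0.856 without control 3. Over the fits without 1 library the adjusted p ran from 0.705 to 1 for the apoptosis list, from 0.0839 to 0.883 for the NRF2 and oxidative stress list, from 7.58e-24 to 0.856 for the hypoxia and glycolysis list and from 0.000134 to 0.342 for the cytosolic ribosomal proteins list. At 14580261 to 17004337 counts per library, changes of 0.5 (log2) were recovered in 35.2% of simulated genes, so unlisted genes are not shown to be unchanged.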

Other observations

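The tests on control 1 as the cause of the rises and of the mitosis list, on depth, on a wrong label and on a difference between cultures were chosen only after the values were seen, as were the tests of transcription factor, synthetase and small nucleolar RNA host gene families and of stress genes against chaperones. Aminoacyl-tRNA synthetases, which charge tRNAs for translation, were split by the form of their symbols into a cytosolic and a mitochondrial set. The symbols do not mark genes that serve both compartments, as GARS does, so the split is rough. Of the cytosolic set 8 of 20 tested genes rose and 0 fell. Of the mitochondrial set 0 of 17 rose by edgeR, DESeq2 or voom, with 1 at an unadjusted p under 0.05. The family was picked because its members were seen to rise, so a p of 0.00389 for the difference in these shares (two-sided Fisher's exact test) decides nothing. Of examples picked after their values were seen, YARS rose 1.72-fold from 113 ± 23.5 to 194 ± 8.43 CPM (n = 3 per group) and TARS 1.59-fold from 200 ± 20.1 to 318 ± 6.71 CPM, while MARS, 1 of the 8, overlaps DDIT3, and 4 of the 20 genes belong to the stress response list. The median of the cytosolic genes was 0.23 (log2), and that of control 1 against controls 2 and 3 was -0.245. Without control 1, 11 rose and the median was 0.19, while 1 mitochondrial gene rose.

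Long noncoding host genes of small nucleolar RNAs rose in 5 of 19 tested genes, GAS5, SNHG1, SNHG8, SNHG15 and SNHG17, chosen after their values were seen, with 0 that fell. They too were picked for their rise, so an odds ratio of 13.8 against all other tested genes restates it. SNHG1 rose 1.62-fold from 48.1 ± 3.35 to 77.9 ± 2.04 CPM and GAS5 1.52-fold from 69.9 ± 12.9 to 107 ± 2.82 CPM. In control 1 their median was -0.05 against controls 2 and 3, and without control 1, 9 rose. MIR616, which lies inside DDIT3, and SLC7A11-AS1 and VLDLR-AS1, which overlap SLC7A11 and VLDLR, also rose, picked in the same way, and their reads could belong to the overlapping gene.

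Among the transcription factor families annotated in the deposited table, basic leucine zipper factors rose in 11 of 44 tested genes (odds ratio 13.1, two-sided Fisher's exact test, adjusted p 2.5e-07 over 27 families), with 0 that fell. They were ATF3, ATF4, CREB5, DDIT3, FOS, JDP2, JUN, JUND, NFE2L2, NFIL3 and XBP1, and 8 of them belong to lists fixed in advance, so their rise is in part reported above. The family tests were chosen after the values were seen and treat genes as independent, so their p decide nothing. Basic helix-loop-helix factors (6 of 44 rose and 2 fell, odds ratio 6.11, adjusted p 0.0111) and ETS factors (4 of 20 rose and 0 fell, odds ratio 9.64, adjusted p 0.0131) had high odds ratios by the same test too. Over the tested members of these 3 families control 1 had medians of -0.13, 0.002 and -0.189 against controls 2 and 3, and without control 1, 22, 10 and 4 rose and 2, 5 and 3 fell. The stress response list less the chaperone list, in mean log2 CPM, was -1.66, -0.913 and -0.998 in the controls and 0.10, -0.07 and 0.12 in the treated libraries, a difference of 1.24, which restates the medians of the 2 lists and was not taken as a test.

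Control 1 lay apart from controls 2 and 3. Its depth of 16.9 M counts lay within the range of the other libraries, and after a correction for GC content and transcript length its hypoxia and mitosis medians were -0.806 and 0.815 (log2), from -0.842 and 0.759, against controls 2 and 3. A treated library under a wrong label would share the rise of cholesterol synthesis, where its median was 0.0545 against 0.738 in the treated libraries. A different cell line in the tube would show genes switched on or off, and 0 genes at 5 CPM or more in both other controls were under 0.5 CPM in control 1 or the reverse, against 1 in control 2. That count cannot exclude a partial mixture or a closely related line, which need not switch genes fully on or off. What also stays open is a difference in density, medium or handling, which the labels do not describe, or in RNA quality or library preparation. None of these was tested.

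The rise of stress response and cholesterol synthesis genes did not rest on control 1, since without it the medians were 0.854 and 0.744. The reverse of the difference that set control 1 apart would take hypoxia genes up with stress genes. Hypoxia genes were lower in the treated libraries than in controls 2 and 3 (median -0.319), as in control 1 (-0.842). Stress genes were higher in the treated libraries (0.85) and lower in control 1 (-0.822). This test, chosen after the values were seen, covers only that 1 kind of difference and cannot exclude another between cultures. After the GC and length correction the stress response and cholesterol synthesis medians were 1.19 and 0.768. The 10 splits of the 6 libraries are too few for a share under 0.05, and the real split gave 703 changed genes and 114 at 2-fold, the highest of the 9 others 0 and 0 by edgeR (171 to 797 genes at an unadjusted p under 0.05, against 3276), with 1 of 10 splits reaching the real count. Each of the 9 others mixes treated and control libraries in both groups. Any difference between treated and control libraries then widens the spread within groups, so their 0 does not weigh against chance. For lists called by camera with the preset correlation, 5 of 10 splits reached the real count of 14, and the highest other also called 14, so that count does not set the real split apart. The cholesterol synthesis list lay at 0.715, 0.794 and 0.821 in the treated libraries and at -0.000861, 0.0199 and -0.019 in the controls, against the mean of the controls. Treatment, the difference that the labels give, remains a candidate cause of the rises, as a hypothesis, and no label names a batch.

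The fall of the mitosis list went with control 1. Without that library the median was 0.00233, with 4 of 35 members that fell, by log2 -0.304 at most, and 2 that rose, and in the full comparison 0 of 35 members passed by edgeR and voom, 2 by DESeq2 and 8 at an unadjusted p under 0.05. These data may therefore hold no fall of the mitosis list as a whole with TCDCA, while a fall of single members such as ASPM stays open.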
